A study of Rattus norvegicus with 10 samples.

How the data were processed

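Rat brain RNA was measured on single-colour oligonucleotide arrays. The 10 samples came from 5 regions, the amygdala, caudate putamen, nucleus accumbens, prefrontal cortex and ventral tegmental area, and each region had 1 array from cocaine-treated and 1 from saline-treated rats. The dose, route and length of treatment, the time of dissection and whether a sample held tissue of 1 animal or of several are not given in the sources used here. Groups were taken from the sample labels, and the arrays of a region were treated as a pair because the labels name the same region.

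The deposited values are intensities on a linear scale, which the authors, per the labels, computed as the expression index of dChip, a program that fits a model to the probes of each probe set. The dChip version, the model and the scaling between arrays are not given in the sources used here. The medians of the deposited columns lay between 2208 and 2310, and the largest index on each array between 45594 and 64907. A spike-in control and Apoe lay near that largest value where they were above 0, so differences between the most abundant transcripts may be compressed. The table held 8799 probe sets, of which 59 control probe sets were left out. Of the other 8740, the annotation table gave 1 gene symbol for 7006, several for 308 and none for 1426. All 6994 single symbols that could be looked up in the current rat gene table stood unchanged. Only probe sets with 1 symbol are named.

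Exact zeros made up 593 values in 511 probe sets, 0.678% of all values. Not all were low measurements, since 69 fell on probe sets whose other arrays had a median in the top 5% of all values, and Cst3, Apoe and a spike-in control were among the probe sets listed at 0 on some arrays. The design fixed before the data were examined would have raised zeros to the floor like other low values. They were instead treated as having no value. That choice was made after both versions had been fitted and their counts seen, so the counts with zeros raised to the floor are given beside the main ones. Other choices made after the data were seen were to take the floor percentile over values above 0, to let only probe sets with a value on all 10 arrays stand for a gene in the gene lists, and to leave ribosomal protein kinases out of the ribosomal protein list. The lists of genes of other organs and of hypothalamic neurons were also written after the data were seen.

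No further normalization was applied. Values below the 20th percentile of all values above 0, an index of 1028, were raised to it before log2 was taken, and the 5244 probe sets in the upper 60% by mean index were tested. Tests were run with limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The first comparison, cocaine against saline across the 5 regions, had region as a block and 4 residual degrees of freedom. The second set each region against the mean of the other 4 with treatment as a term. The third was the interaction of treatment with region class, the caudate putamen and nucleus accumbens against the other 3 regions, with 3 residual degrees of freedom. Within a region, 1 array stood against 1 array, so only log2 ratios and the count of probe sets with a fold of at least 1.5 were taken. The labels do not say whether samples come from separate animals, so the p-values measure the spread between these samples and regions, which may be technical in part. The number of arrays limits the precision of every value.

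The 23 gene lists were fixed before the data were examined. A gene was represented by its probe set with the highest mean, which gave 3093 genes. Lists were tested across the regions with limma's camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation and with fry beside it. Camera compares a list with the other genes, while fry tests whether the genes of a list move, on balance, one way and compares them with no other genes. Within a region, the median log2 ratio of a list was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. Such a percentile describes these arrays and is not a p-value. The rule for named genes was also fixed beforehand. Across the regions it took the 10 highest and 10 lowest probe sets past the threshold with the same sign in all 5 regions, filled by the smallest p where fewer passed. For each region it took the 5 highest past the threshold and the members of the marker lists. For the striatal comparison it took the 5 highest and 5 lowest, filled in the same way. Within a region it took the 5 highest and 5 lowest log2 ratios with both values above the floor and the higher at or above the median. From each list it took up to 4 members with the largest change, and from the immediate early list also Fos, Fosb, Junb, Egr1, Nr4a1, Arc and Homer1 where measured.

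The alternatives chosen before the data were examined were median scaling, quantile normalization, floors at the 10th and 40th percentile, a pseudocount in place of the floor, no filter, the upper 40% of probe sets, no intensity trend, array weights, no region block, and leaving out each region or each array in turn. Alternatives added after the data were seen were zeros raised to the floor, leaving out the amygdala and prefrontal cortex together, and a covariate made of each array's median log2 index over 186 probe sets of 115 genes of other organs. The fits were tested on simulated data in which each probe set had its spread on these arrays and independent noise. Differences shared by many probe sets of an array were not simulated, so the rates that follow may not hold for the real arrays. Across the regions, 90 of 100 probe sets shifted by 0.5 on the log2 scale and 100 of 100 shifted by 1 were called, with 19 of 4694 unshifted probe sets. For 1 region against the others the calls were 66 and 99 of 100, with 13 unshifted, and for the striatal interaction 10 and 76 of 100, with 4 unshifted. Camera called a simulated list shifted by -0.15 and 0 of 20 unshifted lists. Figures were drawn with matplotlib 3.10.9.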

Results

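Expression of 8740 non-control probe sets was measured in 5 regions of the rat brain, each with 1 array from cocaine-treated and 1 from saline-treated rats. Cocaine is a psychostimulant that blocks the reuptake of dopamine, and the regions sampled are the ventral tegmental area, where dopamine neurons lie, and areas that their axons reach. The median expression index of an array lay between 2208 and 2310. Across 5244 tested probe sets, the arrays of a region correlated with r of 0.992 in the caudate putamen, 0.988 in the nucleus accumbens, 0.978 in the ventral tegmental area, 0.953 in the prefrontal cortex and 0.940 in the amygdala. The cocaine array of the prefrontal cortex stood farthest from the rest, with a median r of 0.912 with the other arrays and 226 exact zeros, against 18 on its saline partner. No region had more than 1 array per treatment. Each SD of a region given below (n = 2) is thus taken over 1 saline and 1 cocaine array and includes any difference between them.

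The caudate putamen and nucleus accumbens, which form the striatum, were set apart by genes of striatal projection neurons. Drd1, the dopamine receptor of the direct pathway, had an index of 10952 ± 68.5 (SD, n = 2) in the caudate putamen and 8201 ± 49.8 (SD, n = 2) in the nucleus accumbens, 4.81-fold and 3.35-fold above the mean of the other 4 regions (limma adjusted p = 2.58e-05 and 0.000198). Tac1, the substance P precursor, was 4.76-fold and 3.32-fold higher (limma adjusted p = 0.000649 and 0.00828). Of 14 measured markers of these neurons, 13 were higher in the caudate putamen and 7 in the nucleus accumbens, while 11 were lower in the prefrontal cortex and 11 in the ventral tegmental area. Adjusted over the list alone, the counts were 13, 11, 12 and 11. The caudate putamen was further marked by Arpp21, a phosphoprotein regulated by cyclic AMP, 5.82-fold higher, and by Rgs9, which shortens G protein signalling, 3.65-fold higher. In the nucleus accumbens, Cartpt, a peptide precursor induced by psychostimulants in some studies, was 2.83-fold, Pcp4l1 2.64-fold and Gnal, the olfactory type G protein subunit that couples dopamine receptors to adenylyl cyclase, 2.60-fold above the same mean. All folds between regions come from limma's fit on the log2 scale, so they compare geometric means and differ from ratios of mean indices. For Drd1, Arpp21 and Gnal, some values in the prefrontal cortex or ventral tegmental area lay below the floor of 1028 and were raised to it.

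Several transcripts of cortical excitatory neurons were higher in the prefrontal cortex than the mean of the other regions. Cck, a neuropeptide precursor, had an index of 27877 ± 334 (SD, n = 2) there, 2.92-fold above the mean of the other 4 regions (limma adjusted p = 0.00682). Olfm1 was 2.97-fold, Nrn1, which promotes neurite growth, 2.62-fold, the calmodulin-binding Nrgn 2.58-fold and a probe set of the postsynaptic scaffold gene Homer1 2.53-fold higher. A more abundant Homer1 probe set was instead highest in the caudate putamen, at 6108 and 5934 against 5497 and 4572 in the prefrontal cortex. Of 13 markers of cortical and amygdala excitatory neurons, 5 were higher in the prefrontal cortex, while in the ventral tegmental area 9 were lower and 1 higher. Myelin genes went the other way, with 8 of 16 lower in the prefrontal cortex, among them Mobp at 2.05-fold and Cnp at 1.78-fold lower, and 9 of 16 higher in the ventral tegmental area. Adjusted over the list alone, the excitatory counts were 6, 9 and 2 and the myelin counts 11 and 12.

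In the ventral tegmental area, Calb2, the calcium-binding protein calretinin, had an index of 12815 ± 966 (SD, n = 2) and was 4.67-fold above the mean of the other 4 regions (limma adjusted p = 5.23e-05). Th, the rate-limiting enzyme of dopamine synthesis, was 2.55-fold and Aldh1a1 2.48-fold higher, and of 10 dopamine neuron markers 3 were higher and 1, Drd2, lower, or 4 and 1 adjusted over the list alone. Hcrt, the orexin precursor made by hypothalamic neurons, was 4.19-fold higher with an index of 15218 ± 11893 (SD, n = 2), and the secretory proteins Scg2 and Resp18 were 3.89-fold and 3.67-fold higher. Cartpt was 3.50-fold higher. In the amygdala, Ttr, a thyroid hormone carrier abundant in choroid plexus, was 9.07-fold higher with an index of 35298 ± 8283 (SD, n = 2, limma adjusted p = 0.0109), and the caudate putamen also had a 4.43-fold excess of Ttr, at 22766 ± 16328 (SD, n = 2). Also above the mean of the other 4 regions in the amygdala were Olfm1 at 2.41-fold, the synaptic vesicle protein Sv2b at 2.15-fold, Gda at 2.12-fold and the enkephalin precursor Penk at 1.74-fold. The amygdala was not the highest region for all of them: Penk stood at 17900 and 15372 there but at 28595 and 27745 in the caudate putamen, and Olfm1 reached 16957 on a prefrontal array.

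Past the threshold were 32 probe sets in the amygdala, 214 in the caudate putamen, 28 in the nucleus accumbens, 265 in the prefrontal cortex and 580 in the ventral tegmental area, of 5232 tested in limma. With a fold of at least 2 these became 8, 44, 12, 40 and 86. The higher and lower calls numbered 21 and 11, 91 and 123, 24 and 4, 71 and 194, and 411 and 169, respectively. Under median scaling, the majority in the caudate putamen turned, with 94 higher and 85 lower. Under quantile normalization, the split moved to 72 and 108 in the prefrontal cortex, and the share of higher calls in the ventral tegmental area from 70.9% to 54.6%, with 189 lower. The counts depended on single arrays: the amygdala count was 381 without its saline array, 86 without its cocaine array and 0 without either accumbens array, and the prefrontal count was 54 without its cocaine array. With zeros raised to the floor, as first designed, the counts were 9, 163, 19, 152 and 458.

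**Figure D1:**
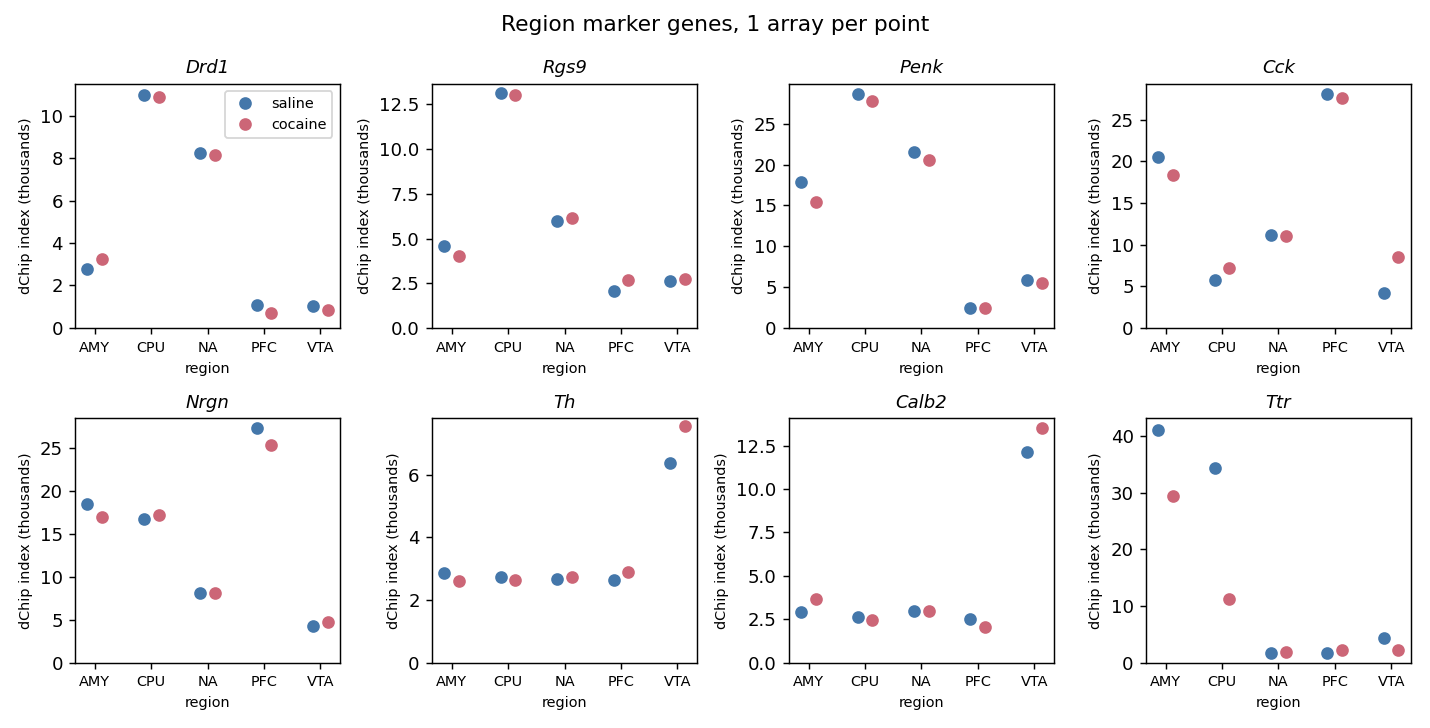
Expression index, on a linear axis, of 8 marker genes on each of the 10 arrays, with blue points for saline and red for cocaine and the regions as AMY (amygdala), CPU (caudate putamen), NA (nucleus accumbens), PFC (prefrontal cortex) and VTA (ventral tegmental area). Drd1 is highest in the caudate putamen at 11001 and 10904, Th in the ventral tegmental area at 6363 and 7544, and Ttr differs between the caudate putamen arrays, at 34312 with saline and 11221 with cocaine.

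Cocaine and saline arrays were then compared across the 5 regions. The genes named here had the same sign in every region and the smallest p. On the lower side, Map2k1, the kinase that activates ERK, had a log2 change of -0.29 ± 0.08 (SE), Cdk17 of -0.26 ± 0.08, the thyroid hormone receptor gene Thra of -0.30 ± 0.09 and the translation factor gene Eif4h of -0.28 ± 0.09. The endoplasmic reticulum chaperones Canx and Hsp90b1 had changes of -0.25 ± 0.08 and -0.25 ± 0.08, the cochaperone Dnaja2 of -0.25 ± 0.09, the respiratory chain gene Ndufab1 of -0.22 ± 0.07, the pyruvate dehydrogenase subunit Pdha1 of -0.17 ± 0.06 and Arrb2, which uncouples receptors from G proteins, of -0.19 ± 0.07. Those on the higher side, Rad18, Sult5a1, Defb4, Enpp1, LOC102554372, Nptx1, Trrap, Pet100, Ahsg and Dusp1, lay between 0.13 and 0.20. None of these 20 genes passed the test.

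In limma, 0 of 5244 probe sets passed the adjusted threshold and 69 had an unadjusted p under 0.05, 8 higher and 61 lower, where chance alone gives 262. So few small p-values show that the test was conservative on these arrays. Ratios that run opposite between regions, as described below, widen its residual spread. The 0 calls therefore do not exclude a change shared by the regions. The count stayed at 0 with zeros raised to the floor. Of 4894 probe sets with a value in every region, 71 were higher and 80 lower in all 5, or 3.09%, below the 6.25% of independent signs. Of 12 named genes with several tested probe sets, 3 had a probe set of the opposite sign, Map2k1, Thra and Ahsg.

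Immediate early genes, which neurons switch on within minutes of activation, gave no common direction. Egr1 had an index of 4401 with saline and 6882 with cocaine in the amygdala but 11016 and 5565 in the prefrontal cortex, on its most abundant probe set, while another Egr1 probe set went the opposite way in both regions. Fos, on its most abundant probe set, stood at 10904 with saline and 8899 with cocaine in the amygdala and at 8490 and 9778 in the prefrontal cortex. A probe set of Homer1 had log2 ratios of 0.61 in the caudate putamen, 0.37 in the nucleus accumbens and 0.43 in the amygdala but -0.37 in the prefrontal cortex, and no other Homer1 probe set was higher in both striatal regions. Arc, Junb and Nr4a1 had log2 changes across the regions of 0.08 ± 0.06, 0.12 ± 0.10 and 0.05 ± 0.06 (SE) on their most abundant probe sets. Of 16 immediate early genes, 0 passed the test, over all probe sets or adjusted over the list alone.

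Of the 23 gene lists, 4 were shifted down with cocaine in limma's camera test at the preset correlation, and none of these calls held with an estimated correlation. Camera with an estimated correlation called 0 lists, with adjusted p = 0.434 for oxidative phosphorylation, 0.431 for heat shock, 0.589 for ribosomal proteins and 0.516 for astrocytes, and fry called 0 lists, with adjusted p = 0.567, 0.567, 0.703 and 0.604. At the preset correlation, oxidative phosphorylation genes were lower in 44 of 49 members with a median log2 change of -0.09 (adjusted p = 2.72e-08), led by the complex I genes Ndufb6 at -0.31 ± 0.12 and Ndufb5 at -0.29 ± 0.14 (SE). Heat shock and unfolded protein response genes were lower in 22 of 23 with a median of -0.10 (adjusted p = 7.39e-06), led by Hsph1 at -0.30 ± 0.13 and Dnaja1 at -0.29 ± 0.16. Ribosomal protein genes were lower in 28 of 33 with a median of -0.08 (adjusted p = 4.49e-05), led by Rpl35a at -0.17 ± 0.11 and Rpl11 at -0.16 ± 0.06. Astrocyte markers were lower in 15 of 17 with a median of -0.03 (adjusted p = 0.0369), led by Vim at -0.21 ± 0.11 and Clu at -0.18 ± 0.11. In each list 0 members passed limma's test, over all probe sets or adjusted over the list alone. The ribosomal median was -0.26 in the prefrontal cortex and 0.04 in the nucleus accumbens, and without the prefrontal pair the ribosomal and astrocyte calls were lost, with camera adjusted p = 0.591 and 0.399.

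The other 19 lists did not pass in camera. Nearest were MAP kinase, PKA, PKC and CaMK signalling, lower in 31 of 45 members (adjusted p = 0.0701), and glucocorticoid-responsive genes, higher in 8 of 12 (adjusted p = 0.0904). Neuropeptides were lower in 13 of 21, synaptic vesicle and release proteins in 27 of 36, cytoskeleton and neurite growth genes in 26 of 38 and myelin genes in 13 of 16 (each adjusted p = 0.188). Monoamine receptors, transporters and enzymes had an adjusted p of 0.208, neurotrophins and growth factors 0.240, microglia and immune markers 0.278, markers of neighbouring brainstem, thalamic and hypothalamic neurons 0.278, immediate early genes 0.348, dopamine neuron markers 0.348 and endothelial, mural and blood cell markers 0.413. Choroid plexus markers and glutamate receptors each had 0.517, G protein regulators 0.518, excitatory neuron markers and GABA genes each 0.662, and striatal projection neuron markers 0.811. Signs differed between measures for excitatory neuron markers, with a median of -0.03 but an upward camera direction, for GABA genes, with a median of 0.02 and a mean of -0.02, and for striatal and endothelial markers, whose medians and means lay within 0.01 of 0. Among their leading members, Cck had a log2 change of 0.23 ± 0.16, Gad1, which makes GABA, of -0.28 ± 0.18 and Sst of -0.30 ± 0.21 (SE).

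The striatal response was set against that of the other 3 regions. The largest differences among the genes named for this interaction were those of Zmym3 and of Ptgds, the prostaglandin D synthase of the meninges and choroid plexus. Zmym3 had log2 ratios of 1.47 in the caudate putamen and 0.38 in the nucleus accumbens against 0.24 in the amygdala, -0.26 in the prefrontal cortex and -0.22 in the ventral tegmental area. Ptgds had -0.37 and -1.12 against 0.39, -0.33 and 0.38. The saline value of Zmym3 in the caudate putamen, 868, lay below the floor before log2 was taken. Cxcr4, Rpl21, Tnfsf13 and Snf8 were higher in the striatal regions relative to the rest by 0.48, 0.43, 0.41 and 0.33, and Sult2a2, Pisd, Psap and Epb41 differed by -0.53, -0.49, -0.44 and -0.44 on the log2 scale. None passed the test. In limma, 0 of 5229 probe sets passed the adjusted threshold, with 16 at an unadjusted p under 0.05, where chance alone gives 261. This test was thus conservative too, and its 0 calls do not exclude a striatal difference. Without the amygdala pair the count was 211, and with zeros raised to the floor it was 0. The ratios of the other regions then left, the prefrontal cortex and ventral tegmental area, ran alike (r = 0.576). Those of the striatal regions did not (r = 0.0417), so the 211 need not reflect a shared striatal response.

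Within single regions the changes have no replicate check. In the caudate putamen, 8 probe sets differed by at least 1.5-fold, 2 higher and 6 lower with cocaine. A probe set of Homer1 was 1.53-fold and Slc4a1, the red cell anion exchanger, 1.49-fold higher, followed by Lbh, Armc6 and Pde5a at 1.44-fold, 1.37-fold and 1.34-fold. No other Homer1 probe set was higher with cocaine in the caudate putamen. Ttr was 3.06-fold, Flg 3.04-fold, B3galt4 1.85-fold, Enpp2, an enzyme of oligodendrocytes and choroid plexus, 1.68-fold and the circadian repressor Nr1d1 1.58-fold lower. In the nucleus accumbens, 12 probe sets differed, 3 higher and 9 lower. Lrch4 was 1.52-fold, Cdk5r1, the activator of the neuronal kinase Cdk5, 1.49-fold, Gtdc1 1.45-fold and Uqcc2 1.44-fold higher, and Egfl7 stood at 3633 with saline and 5440 with cocaine. Ptgds was 2.18-fold and Kcnj11, a subunit of the ATP-sensitive potassium channel, 1.83-fold lower, with Tpcn1, Defb1 and Wdr62 at 1.72-fold, 1.68-fold and 1.62-fold lower. The accumbens split was 7 higher and 9 lower under median scaling and 6 and 8 under quantile normalization.

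In the ventral tegmental area 85 probe sets differed, 46 higher and 39 lower with cocaine, or 31 and 53 under median scaling and 30 and 42 under quantile normalization. Pvalb, a calcium-binding protein of fast-spiking neurons, was 2.25-fold and Cck 2.04-fold higher, with Defb1 and Tpcn1 at 2.20-fold and 2.11-fold, and Man2c1 stood at 3841 with saline and 7698 with cocaine. Hcrt was 3.47-fold, Sst 2.59-fold, Cdc5l 2.13-fold, Gad1 2.10-fold and Ttr 1.92-fold lower. Th stood at 6363 with saline and 7544 with cocaine, and the median log2 ratio of the dopamine neuron markers, 0.29, lay at percentile 100 of matched random lists. The median over genes of other organs in this region was 0.12. Only 3 of the 10 dopamine neuron markers passed as higher in this region than in the others. In the prefrontal cortex the same list had a median of 0.25, at percentile 98.3. The percentile therefore does not single out a change in dopamine neurons.

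In the amygdala 458 probe sets differed, 73 higher and 385 lower with cocaine, or 117 and 310 under median scaling and 127 and 307 under quantile normalization. A probe set of Dusp1, a phosphatase that ends MAP kinase signalling, was 2.05-fold, Matr3 1.90-fold, Atp5pb 1.87-fold and Phrf1 1.87-fold higher, and Insig1, a regulator of sterol synthesis, stood at 1184 with saline and 2373 with cocaine. The other tested Dusp1 probe sets disagreed, with log2 ratios of -0.384 and 0.185 in the amygdala. Defb1, a beta-defensin, was 3.30-fold, Wdr62 3.12-fold, the endolysosomal channel Tpcn1 2.97-fold, the nuclear receptor Pparg 2.78-fold and the kinase Gsk3b 2.72-fold lower. In the prefrontal cortex 249 differed, 162 higher and 87 lower, or 109 and 153 under median scaling and 155 and 125 under quantile normalization. Kcnj11 was 3.01-fold, Tpcn1 2.95-fold, Defb1 2.92-fold and Wdr62 2.86-fold higher, and Cdk2 stood at 1301 with saline and 3898 with cocaine. Egr1 was 1.98-fold, the chemokine Cx3cl1 1.91-fold, the cannabinoid receptor gene Cnr1 1.87-fold, Oaz1 1.86-fold and Nr2f1 1.85-fold lower. With zeros raised to the floor, the counts were 544 in the amygdala, 20 in the caudate putamen, 24 in the nucleus accumbens, 411 in the prefrontal cortex and 177 in the ventral tegmental area.

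The log2 ratios of the amygdala and the prefrontal cortex ran opposite to each other, with r = -0.624 across 4894 probe sets, which are not independent replicates. The ratios of the amygdala and the ventral tegmental area gave r = -0.587, those of the prefrontal cortex and the ventral tegmental area r = 0.576, and the other 7 pairs of regions lay between -0.202 and 0.207. Defb1, which had an index of 6104 with saline and 1847 with cocaine in the amygdala, stood at 2162 and 6306 in the prefrontal cortex. The median log2 ratio over 186 probe sets of 115 genes of other organs, such as liver and muscle, was -0.19 in the amygdala, 0.19 in the prefrontal cortex, -0.01 in the caudate putamen and 0.01 in the nucleus accumbens.

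**Figure D2:**
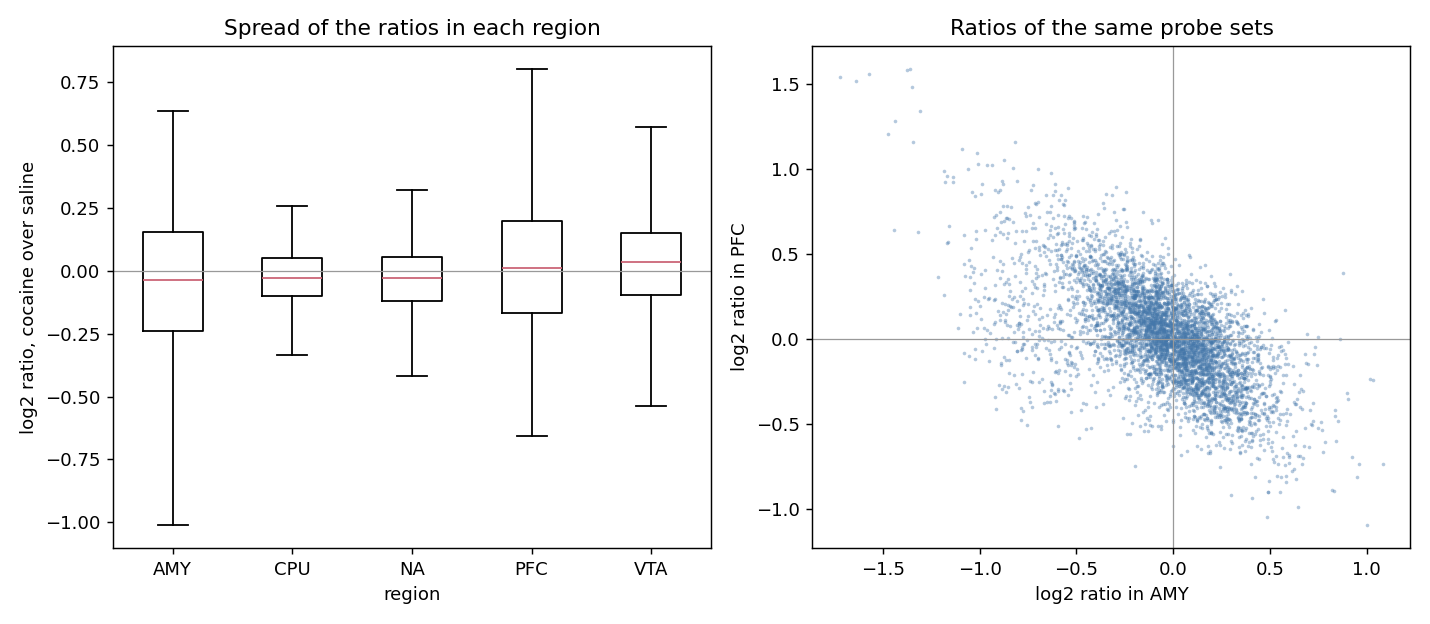
Left, log2 ratio of cocaine over saline in each region over the tested probe sets, with boxes for the quartiles, red lines for the medians and whiskers at the 1st and 99th percentiles; right, the ratio of each probe set in the prefrontal cortex (PFC) against that in the amygdala (AMY). The standard deviation of the ratios is 0.33 in the amygdala and 0.29 in the prefrontal cortex but 0.13 in the caudate putamen, and the ratios in the right panel run opposite, with r = -0.624.

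Some gene lists, though not all, differed in direction between the amygdala and the prefrontal cortex or ventral tegmental area. Immediate early genes had a median log2 ratio of -0.33 in the amygdala, at percentile 0.03 of matched random lists, but 0.24 in the prefrontal cortex and 0.18 in the ventral tegmental area, at percentiles 99.8 and 99.9. Neurotrophins and growth factors were likewise at percentiles 0.25, 99.4 and 98.1, and endothelial, mural and blood cell markers at 0.38 in the amygdala and 99.8 in the ventral tegmental area. Dopamine neuron markers lay at 98.3 in the prefrontal cortex. Oxidative phosphorylation genes lay at 0.09 in the amygdala and 0.01 in the caudate putamen, and heat shock genes at 0.48 in the caudate putamen and 0.18 in the prefrontal cortex. Ribosomal protein genes lay at 0 in the prefrontal cortex and 0.12 in the ventral tegmental area but at 99.7 in the nucleus accumbens, where glutamate receptors lay at 100, glucocorticoid-responsive genes at 99.9 and choroid plexus markers at 98.8. Myelin genes lay at 0.36 in the caudate putamen and 98.8 in the ventral tegmental area, neuropeptides at 1.01 in the ventral tegmental area, MAP kinase and related signalling genes at 2.20 and excitatory neuron markers at 97.6 in the caudate putamen, and cytoskeleton genes at 98.4 in the amygdala and 1.23 in the prefrontal cortex. In all, 5 lists in the amygdala, 5 in the caudate putamen, 4 in the nucleus accumbens, 6 in the prefrontal cortex and 7 in the ventral tegmental area lay among the 2.5% highest or the 2.5% lowest of random lists, where 1.15 of 23 unrelated lists would. That number holds for genes that vary independently. The estimated correlation was 0.376 among immediate early genes and 0.292 among ribosomal protein genes, though -0.058 among striatal markers, and some lists share members. The counts therefore do not measure an excess over chance.

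**Figure D3:**
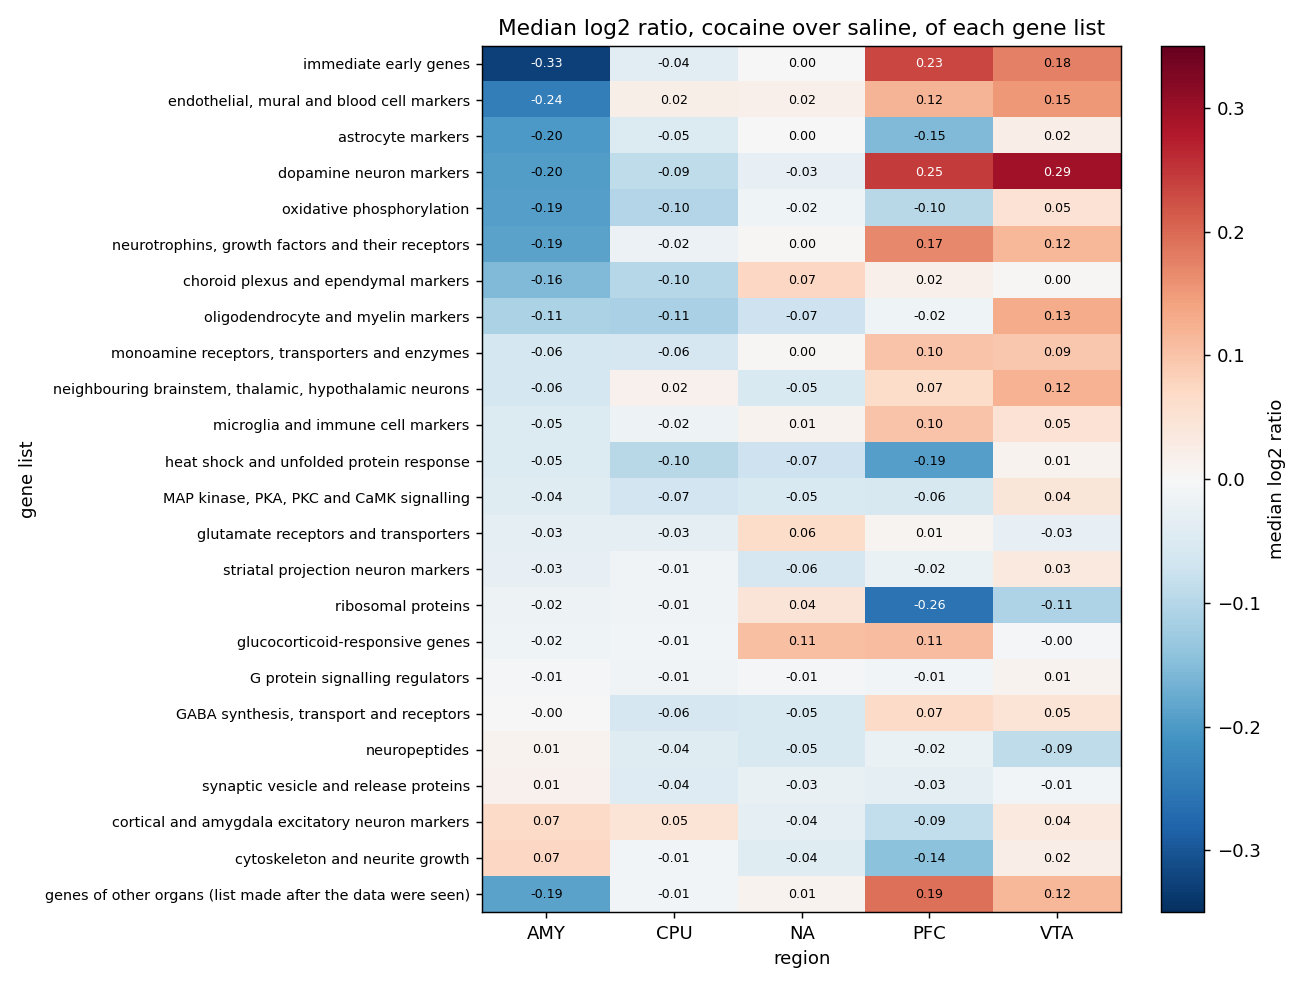
Median log2 ratio of cocaine over saline of the 23 gene lists in each region (abbreviated as in the plot of marker genes), with a last line for genes of other organs, a list made after the data were seen. That line is taken over probe sets without the floor or filter. Red is higher and blue lower with cocaine. Immediate early genes are at -0.33 in the amygdala and 0.24 in the prefrontal cortex, and genes of other organs at -0.19 and 0.19.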

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

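All list tests of the striatal difference in this part were chosen after the data were seen. In a camera test of the interaction, ribosomal protein genes and oxidative phosphorylation genes were called as differing between the striatal regions and the other 3, at the preset correlation only. The mean of the striatal list medians exceeded that of the other regions by 0.145 on the log2 scale for ribosomal proteins (adjusted p = 6.21e-09) and by 0.0207 for oxidative phosphorylation (adjusted p = 0.00498). With an estimated correlation neither call held, with adjusted p = 0.951 for each. The ribosomal medians were -0.01 in the caudate putamen and 0.04 in the nucleus accumbens against -0.02 in the amygdala, -0.26 in the prefrontal cortex and -0.11 in the ventral tegmental area. The lowest of these was that of the prefrontal cortex, whose cocaine array stood apart from the others. The oxidative phosphorylation medians were -0.10 and -0.02 against -0.19, -0.10 and 0.05, so the striatal medians lay within the range of the others. Of the 10 ways to take 2 of the 5 regions, 5 gave at least the 2 lists called here, and the highest of the others gave 5. So few pairs cannot give a share under 0.05, and for probe sets, where the real pair and the highest other both gave 0, the count of 10 of 10 pairs cannot inform.

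Several genes had ratios of opposite sign in the striatal regions and in every other region with a value. Cxcr4, a chemokine receptor gene, differed by 0.48 on the log2 scale, Tnfsf13, a cytokine gene, by 0.41, and Snf8, of the endosomal sorting machinery, by 0.33, each higher in the striatal regions. Sult2a2 differed by -0.53, Pisd, which makes phosphatidylethanolamine in mitochondria, by -0.49 and Epb41 by -0.44. Sult2a2 and Pisd were listed at 0 on the cocaine array of the amygdala, so that region has no ratio for them. These genes were named because they had the smallest p in the interaction, and none passed it. Over all tested probe sets, 145 had such opposite signs, 2.77% against 6.25% for independent signs.

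For the gene lists across the regions, chance could not be excluded. Of 100 drawn splits of the 10 arrays into 5 and 5, the real one included, 33 gave at least its 4 lists, with 7 in the highest other. With region as a block, however, a pair kept on one side adds nothing to the estimate. Most drawn splits thus rest on fewer pairs than the real one, and some repeat the same fit. The 33 is therefore not a rate expected by chance. For probe sets the count of splits cannot inform, because the real split gave 0 and every split gives at least that, 100 of 100. The highest other split gave 1373 probe sets, which points to a structure of the arrays. It set the amygdala cocaine array and the prefrontal and ventral tegmental saline arrays on one side and their partners on the other, so it restates the opposite ratios of these regions and does not tell a technical difference from a response to cocaine that differs between them. The splits that parted only the amygdala pair gave 165. Among the 16 splits that part all 5 pairs, as the real one does, 5 gave at least 4 lists, the real one included. The highest other gave 5.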

How the results depend on the processing

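The tests with zeros raised to the floor, without the amygdala and prefrontal cortex together, and with a covariate from genes of other organs were chosen after the data were seen. The count across the regions was 0 under every alternative, and the 20 genes named there kept their sign in 356 of 356 refits. These genes had been chosen for having the same sign in every region. Leaving out regions, or changing the filter, trend, array weights or region block, therefore could not turn their sign. For those refits the kept signs cannot inform. The striatal count was 0 except for 2 with array weights and 211 without the amygdala pair, so leaving out a region gave 0 to 211. The counts for single regions, in the order amygdala, caudate putamen, nucleus accumbens, prefrontal cortex and ventral tegmental area, were 3, 128, 10, 74 and 350 without a filter. Array weights gave 6, 665 and 78 for the first 3, median scaling 17 for the amygdala, and zeros raised to the floor 9 for the amygdala and 152 for the prefrontal cortex. Leaving out each array in turn, with the lone array left in its region assumed to vary like the others, gave 0 to 381, 22 to 503, 3 to 71, 54 to 647 and 118 to 949. Genes named for a region kept their direction in all refits, with 455 still past the threshold and 43 not.

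Within regions, the counts with a fold of at least 1.5 were 230, 5, 80 and 25 in the amygdala, nucleus accumbens, prefrontal cortex and ventral tegmental area with a pseudocount, which shrinks the ratios of dim probe sets by construction. In the upper 40% by mean, with fewer probe sets, they were 304, 5, 5, 118 and 51 in the 5 regions, and with no filter 403 in the prefrontal cortex. Zeros raised to the floor gave 20, 24, 411 and 177 in all but the amygdala. The ratios of genes named within a region stayed near the main value in 347 refits and moved, without changing sign past the fold threshold, in 34. The number of lists at extreme percentiles within a region stayed within 1.5 times under every scaling and floor.

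Camera called 4 lists, but 2 under quantile normalization, 2 with the covariate, 0 with an estimated correlation and 0 with fry, and leaving out a region gave 2 to 6. Heat shock genes failed only with the estimated correlation and with fry. Oxidative phosphorylation failed there and without the amygdala and prefrontal cortex together, with adjusted p = 0.0891. Ribosomal proteins failed also under quantile normalization (adjusted p = 0.129), without the prefrontal pair (0.591), without the ventral tegmental pair (0.0743), without the amygdala and prefrontal cortex (0.0935) and with the covariate (0.982). Astrocyte markers failed under quantile normalization (0.458), in the upper 40% (0.197), without the amygdala (0.411), caudate putamen (0.0573) or prefrontal pair (0.399) and with the covariate (0.455), and turned upward, not past the threshold, without the amygdala and prefrontal cortex (0.788). Except where the construction is named, the cause was not tested.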

Other observations

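Of the tests in this part, those of degradation, of exchanged arrays, of hypothalamic tissue and of choroid plexus, and the array-wide tests for the ventral tegmental area and the caudate putamen, were chosen after the results they use had been seen. Further members of the gene lists differed between the regions. Heat shock and unfolded protein response genes were higher in the ventral tegmental area in 7 of 23 members past limma's threshold, among them the endoplasmic reticulum proteins Canx at 1.77-fold, Pdia3 at 1.77-fold and Hspa5 at 1.74-fold (adjusted p = 0.00147, 0.0113 and 0.0134). Oxidative phosphorylation genes were higher in 10 of 49 and lower in 1, with Ndufb10 at 1.59-fold higher and Uqcr11 at 1.42-fold lower. Astrocyte markers were higher in 7 of 17, with Agt, the angiotensin precursor, at 3.35-fold and Vim at 2.13-fold. Adjusted over the list alone, these counts were 10, 11 and 1, and 7. On the list of MAP kinase, PKA, PKC and CaMK signalling, 7 of 45 genes were lower and 1, Prkaca, higher, with Pde2a at 3.40-fold and Prkcb at 2.81-fold lower, and among glutamate receptor genes 4 of 30 were lower, with Gria2 at 1.57-fold (11 lower and 3 higher, and 4 lower, adjusted over the list alone). In the prefrontal cortex, 7 of 33 ribosomal protein genes, 5 of 49 oxidative phosphorylation genes and 3 of 23 heat shock genes were lower, with Rps6 at 1.47-fold and Hspd1 at 1.49-fold lower (16, 10 and 5 adjusted over the list alone). The prefrontal cocaine array, which stood apart from the others, was itself lower than its saline partner on these lists, with median log2 ratios of -0.26, -0.10 and -0.19, and the list counts were not computed without it. In the caudate putamen, 8 of 36 synaptic vesicle genes and 8 of 38 cytoskeleton genes were lower, among them Syp at 2.15-fold and Basp1 at 2.04-fold lower (9 and 18 adjusted over the list alone). The 3' to 5' ratio of beta-actin also differed between regions. On saline and cocaine arrays it was 1.22 and 1.27 in the ventral tegmental area and 1.19 and 1.34 in the nucleus accumbens. It was 1.65 and 1.61 in the prefrontal cortex, 1.63 and 1.70 in the caudate putamen and 1.53 and 1.36 in the amygdala. Whether RNA degradation shaped these region differences was not tested.

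The list of genes of other organs was made after the opposite ratios had been noticed, but before its own medians were computed. The opposite ratios of the amygdala and prefrontal cortex were weighed against technical sources. RNA degradation of the prefrontal cocaine sample is argued against by its beta-actin 3' to 5' ratio, which was 0.979 times that of its saline partner, and by that of Gapdh, 1.07 times. For the amygdala saline sample these ratios were 1.13 and 1.02 times those of its cocaine partner, a slight lean toward degradation. An exchange of the amygdala saline and prefrontal cocaine arrays is argued against by striatal markers, which were higher by 0.69 on the log2 scale on the amygdala array, as they were by 0.59 between the other 2 arrays. An array-wide signal difference predicted opposite shifts of genes that belong to other organs, and their median ratio was 0.194 in the prefrontal cortex (95% bootstrap interval 0.157 to 0.250) and -0.187 in the amygdala (-0.224 to -0.125). These medians cover 186 probe sets of 115 genes, taken without the floor and the filter. The intervals resample probe sets of 1 pair of arrays, so they do not measure the spread between arrays. An array-wide difference may account for part of the opposite ratios, immediate early genes included. A cocaine response that differs between the amygdala and the prefrontal cortex stays open and was not tested. With 1 array per treatment in each region, it cannot be told apart from a difference between arrays.

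The lower Hcrt on the cocaine array of the ventral tegmental area is another pattern, with an index of 23627 with saline and 6808 with cocaine. Sst was also lower there, at 9413 and 3638, but stood at 10774 and 13294 in the amygdala, so its level does not mark hypothalamic tissue. A shift of all signals downward is argued against by the genes of other organs, whose median ratio there was 0.115, in the opposite direction. An array-wide difference of the kind seen in the prefrontal cortex cannot be excluded by it. In that region the same median was 0.194, while Scg2 and Gad1 had ratios of -0.416 and -0.465 and Hcrt 0.339. A smaller share of neighbouring hypothalamic tissue in the cocaine sample is a candidate explanation that stays open. The median over 15 other genes of hypothalamic neurons was -0.043 (95% bootstrap interval over genes -0.387 to -0.009). Most of them did not pass limma's test as higher in this region. Of those that did, Cartpt, Scg2 and Resp18 had ratios of -0.68, -0.68 and -0.33 and Nnat 0.01. Probe sets of the peptide genes Pmch, Gal and Oxt were listed at 0 on the saline array here, so they gave no ratio. A lowering of Hcrt by cocaine also stays open and untested.

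Ttr stood at 34312 on the saline and 11221 on the cocaine array of the caudate putamen, against a mean of 1871 in the nucleus accumbens and prefrontal cortex. An array-wide difference is argued against by the genes of other organs, with a median ratio of -0.00827. A smaller share of choroid plexus in the cocaine sample may be the source, since Enpp2, which choroid plexus also makes in abundance, had a log2 ratio of -0.717, below the range of the other 15 oligodendrocyte markers, -0.44 to 0.23. Enpp2 was already among the genes named as lower in this region when the test was chosen, so its low ratio is no separate support. The other 6 choroid plexus genes had ratios between -0.10 and 0.09 and saline levels of 0.913 to 1.08 times their level in the nucleus accumbens and prefrontal cortex, so they carried no measurable choroid signal to lose. Ttr was also lower with cocaine in the amygdala, from 41154 to 29441, and in the ventral tegmental area, from 4431 to 2310. Enpp2 had log2 ratios of -0.503 and 0.038 in these regions. In the nucleus accumbens and prefrontal cortex, Ttr had ratios of 0.108 and 0.419. A change of Ttr by cocaine stays open and was not tested.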
